A study of Mus musculus with 24 samples.

How the data were processed

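The series held 24 Agilent 1-colour arrays of mouse RNA in 6 groups of 4. Per the labels' protocols, the mice were C57BL/6 males aged 10 weeks. Tumour-associated macrophages (TAM) were isolated from naive mice and from mice 14 days after sepsis was induced, on a density gradient followed by 1 hour of adhesion. Bone marrow cells of naive and post-sepsis mice were grown into unpolarized macrophages (M0) over 7 days in medium with L929 supernatant. Further cultures from naive mice received interferon-gamma at 50 ng/mL and lipopolysaccharide at 10 ng/mL (M1), or, per the label, IL-10 at 20 ng/mL (M2), at day 3 of culture. The labels did not name the tumour line.

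Per the series' design text, TAM came from 3 experiments with 4 mice per group each, and the best 4 of 12 samples per group were chosen by absorbance ratios. The marrow cultures came from 2 experiments with 3 samples per group each, from which the best 4 were taken. Which sample came from which experiment was not stated. The p-values therefore measure the spread between chosen samples, whose origin from separate animals and experiments is only partly described.

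Per the file headers, each scanner file held spot intensity values from 1 array, extracted with Agilent Feature Extraction, with the mm9 build named for the probe annotation. Per the submitters' processing notes the extraction software was version 12.5, whereas the file headers gave 10.7.3.1. Per the file headers, the processed intensity had been background-subtracted and detrended within each array, and nothing in the headers scaled it between arrays. The other deposited columns used were flags for control spots, signal well above background, saturation and non-uniform spots. A value table of log2 values was also deposited by the authors. Every column of that table had the same range, from 5.66 to 18.99, and nearly the same median, between 6.93 and 6.96. No header or label stated how those log2 values were scaled between arrays.

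The ranks of each value table column were compared with those of every scanner file. In 22 of 24 columns the best match was the scanner file of another sample, with a rank correlation of at least 0.979. In those columns the correlation with the sample's own file lay between 0.562 and 0.942. All 24 columns followed the order of the scanner files by slide and position on the slide. The scanner files were therefore the main source, and the value table, as deposited and with its columns rematched, served as an alternative.

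Each array had 62976 spots, of which 59305 were not controls. They covered 55681 probes, and 432 probes had more than 1 spot, whose values were averaged. Processed intensities were log2-transformed and centred on the 75th percentile of each array. A probe was kept when its signal was well above background on at least 3 arrays of at least 1 compared group. Gene names came from a RefSeq table for GRCm38.p6, used for names only. Of the probes, 27656 were named by accession, 3401 by symbol and 321 by synonym, 1775 kept the name in the file and 22528 had no gene symbol. A symbol with several probes was given by the probe with the highest mean signal, and a probe without a symbol stood for itself, so counts of genes include such probes. The 75th percentile of processed intensity ran from 236 to 694 over the 23 arrays used, and no spot was saturated. The number of arrays limits the precision. TAM naive replicate 2 was left out of every main comparison because, per the labels, the submitters had excluded it for low RNA amount and quality.

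Differences were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all probes kept, two-sided, at an adjusted p of 0.05. TAM post-sepsis against TAM naive was fitted on its own 7 arrays, and the comparisons among marrow cultures on their 16 arrays. TAM naive against M0 naive, and the difference between the sepsis effects in TAM and in M0, were fitted on all 23 arrays. Where 1 group was well above background on none of its arrays for a gene, its fold change is given only as a bound, written "at least". A change against a group above background on only 1 or 2 arrays is given as fitted, with that number, and its size is uncertain. The difference between sepsis effects has no bounds. Errors on log2 changes are standard errors of the limma fit. Group scores are given with the SD and compared by two-sided exact permutation tests, whose smallest possible p is 0.0286, both for 4 against 4 arrays and for 4 against 3.

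A total of 29 gene lists was fixed before the data were examined. They were M1 activation, alternative (IL-4 type) activation, IL-10 response, type I interferon response, MHC class II presentation, MHC class I presentation, NF-kB cytokines and chemokines, pro-tumour and angiogenic products, CXCL12 axis and monocyte recruitment, immune checkpoint and tolerance, hypoxia and glycolysis, oxidative phosphorylation, cholesterol biosynthesis, unfolded protein and amino acid stress, and cell cycle. The others were lysosome, complement and apoptotic cell uptake, macrophage identity, inflammatory monocyte, neutrophil and granule, dendritic cell, T and NK cell, B cell, fibroblast and stroma, endothelial cell, melanocyte and melanoma, keratinocyte and epithelium, erythroid, and dissociation and early response. Lists with at least 5 measured members were tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. In each list that passed, the median, the mean and the test had the same sign. In TAM, lists were also compared with 10000 random lists of genes of like signal.

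Genes were named by a rule fixed before the data were examined. It took the 10 largest changes in each direction among genes that passed, or the 5 smallest p in each direction where none passed, then up to 4 members of each list, and a fixed set of genes for each comparison. The M1-minus-M2 signature score of an array was the mean of the 100 genes highest in M1 over M2 minus the mean of the 100 genes highest in M2 over M1. An index of signal on protein-coding against lincRNA probes was the median log2 value of protein-coding probes minus that of the 16251 lincRNA probes.

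The fits were tested on simulated data in which 200 genes were changed at the real genes' spread. At a log2 change of 2 the fit recovered 46% of them in TAM, 70% in M0, 68% for M1, 74% for M2, 72% for M1 against M2, 71% for TAM naive against M0 naive and 35% for the difference between sepsis effects. At a log2 change of 1 it recovered 0% in TAM, 20% in M0, 12% for M1, 17% for M2, 22% for M1 against M2, 12% for TAM naive against M0 naive and 2% for the difference. All recovered genes had the right sign, and no unchanged list was called. The simulated genes varied independently of each other, so this cannot show how list tests behave for correlated genes. Of the genes called in simulated data, 9.80% were false in TAM and 5.26% in M0, above the 5% aimed for, 4.60% for TAM naive against M0 naive, 3.09% for M1 against M2, 1.23% for M1, 1.09% for M2 and 0% for the difference.

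Alternatives were other scalings, filters and thresholds, the slide or the replicate number as a block, array weights, fits restricted to the compared groups or extended to all arrays, TAM naive replicate 2 added back, the value table, and each array left out in turn. Some alternatives were chosen after seeing the data. They were the index as a covariate, arrays centred on the median of protein-coding genes alone, the value table with rematched columns, and list tests against protein-coding genes only. The slide as a block was chosen before the data were examined, while printing its values for single TAM genes was decided afterwards, because the main TAM fit called none.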

Results

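Expression was measured on 24 arrays, 4 for each of TAM from post-sepsis mice, TAM from naive mice, M0 macrophages from post-sepsis marrow, M0 from naive marrow, and M1 and M2 cultures from naive marrow. The 23 arrays used had 56.8% to 69.7% of probes well above background, and the TAM naive array left out had 42.4%. The arrays lay on 3 slides, and each slide held arrays of at least 5 groups. Within groups, pairs of arrays correlated at 0.898 to 0.991 among the arrays used. Values are log2 changes ± SE with limma's adjusted p, n = 4 arrays per group and n = 3 for TAM naive.

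The first comparison asked how TAM from post-sepsis mice differed from TAM of naive mice. Genes of lymphocytes and of MHC class II presentation measured lower in post-sepsis TAM. Cd5, a receptor on T cells, was at -1.98 ± 0.42, the B cell factor Pax5 at -1.73 ± 0.39, and H2-Eb1, a chain of the class II molecule, at -1.76 ± 0.45. Among genes of proliferation and sterol synthesis, Bub1b of the mitotic checkpoint measured higher, at 1.70 ± 0.47, and so did Cyp51 of the cholesterol pathway, at 1.04 ± 0.26. None of these genes passed over all genes: limma called 0 of 28945, while 10928 had an unadjusted p under 0.05. The cell cycle list was not higher within slide 2 (median -0.06), and no list call in TAM held with an estimated correlation. The groups did not overlap in 22.8% of genes, where chance gives 5.71% on average over all splits. Genes can vary together, so the share in 1 split may lie far from that average. The share in other splits was not computed, so the 22.8% does not exclude chance. Without post-sepsis replicate 2, 9709 genes passed.

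With the slide as a block, 9978 of 28945 genes passed, 2300 higher and 7678 lower in post-sepsis TAM. Counts of list members in that fit are to be read against this share of lower genes. In that fit Cd5 was at -2.13 ± 0.19, and within the 3 slides at -2.28, -1.89 and -2.17. Cd8a, a co-receptor of cytotoxic T cells, was above background in naive TAM only, at least 2.54-fold lower in post-sepsis TAM in the main fit. Cd3d was at -3.43 ± 0.39 and Cd3g at -3.30 ± 0.36. The B cell genes Cd79a (-2.27 ± 0.53), Ms4a1 (-3.79 ± 0.84), Pax5 (-1.70 ± 0.28) and Fcer2a (-1.90 ± 0.37) passed as well. Cd79a ran from -3.38 on slide 1 to -0.43 on slide 3. H2-Eb1 was at -1.93 ± 0.24 and Cd74, the class II chaperone, at -1.79 ± 0.24. Cd86, a co-stimulator of T cells, was at -1.97 ± 0.20, Il12b at -1.98 ± 0.32, Acod1, which makes itaconate, at -2.63 ± 0.25, and the neutrophil chemokine receptor Cxcr2 at -2.10 ± 0.26. Ccr7, carried by migrating dendritic cells, was at -2.73 ± 0.43 and Cd209a at -2.08 ± 0.28. On the higher side passed Bub1b (1.67 ± 0.33), Sel1l of protein degradation in the endoplasmic reticulum (1.16 ± 0.23), Cyp51 (1.05 ± 0.24), Fdft1 (1.39 ± 0.33) and the pigment enzyme Tyr (1.32 ± 0.35). Cd3d, Cd3g, Cd79a, Ms4a1, Cd74, Acod1 and Ccr7 were chosen from the lists after their values were seen. Il12b and Cxcr2 were above background on 1 of 4 post-sepsis arrays and Cd3g on 2 of 4, so their sizes are uncertain.

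The genes with the smallest p in the TAM fit all had an adjusted p of 0.114. Higher in post-sepsis TAM were Mucl3 (at least 1.17-fold), Filip1 (1.15 ± 0.22), Esco2 of chromatid cohesion (1.02 ± 0.20), Pgm2 (1.67 ± 0.33) and the melanocortin receptor Mc3r (1.11 ± 0.23). Lower were Cd209a (-2.06 ± 0.27), Cadps2 (-1.87 ± 0.25), Pnma2 (-1.55 ± 0.21), Fmr1nb (-2.13 ± 0.30) and the mast cell protease Cma1 (-1.71 ± 0.25), above background on 2 of 4 post-sepsis arrays. Of the genes chosen in advance for their part in tumour macrophages, none passed in the main fit. With the slide as a block, 3 of them passed, all lower in post-sepsis TAM: Il1b at -2.06 ± 0.26 (adjusted p = 0.0111), Cxcr4, the receptor of CXCL12, at -1.90 ± 0.27 (adjusted p = 0.0111) and Cd274, the ligand of PD-1, at -1.24 ± 0.25 (adjusted p = 0.0136). Each was lower within every slide, Cxcr4 at -2.33, -2.10 and -1.14. The mannose receptor Mrc1 at 1.00 ± 0.32 (adjusted p = 0.0512) and Il10 at -0.72 ± 0.23 (adjusted p = 0.0524) did not pass with that block. Arg1 (-0.06 ± 0.79), Nos2 (0.30 ± 0.58), Vegfa (0.25 ± 0.31), Tgfb1 (0.32 ± 0.25), Ccl2 (0.37 ± 0.84), Tnf (-0.27 ± 0.69) and Cxcl12 (0.43 ± 0.94) passed in neither fit.

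Tests of whole lists against all other genes called 12 of the 29 lists in TAM at the preset correlation. None of the 12 calls held when the correlation within lists was estimated from the data, each with adjusted p = 0.836 with an estimated correlation, and 8 of the 12 held with quantile scaling. The T and NK cell list had a median of -1.86 over 16 genes (adjusted p = 1.9e-05) and none passed over all genes, against 13 lower adjusted over the list alone. The B cell list had a median of -2.08 (adjusted p = 7.0e-04), with 10 of 11 lower adjusted over the list alone, and the MHC class II list -1.62 (adjusted p = 0.0076), with 8 of 11. The dendritic cell list was at -0.98, with 7 of 13 lower in that way, M1 activation at -0.74, with 2 of 19, and the neutrophil list at -1.54, with 0 of 15. With the slide as a block, the genes that passed as lower over all genes were 15 of 16 in the T and NK cell list, 10 of 11 in the B cell list, 9 of 11 in MHC class II, 8 of 13 in the dendritic cell list, 10 of 19 in M1 activation and 9 of 15 in the neutrophil list. In the T and NK cell list, the median within the slides was -2.06, -1.88 and -2.24. That of the B cell list was -3.33, -2.64 and -0.88, and that of the MHC class II list -2.19, -1.81 and -1.25. Lists called higher, all lost with an estimated correlation (adjusted p = 0.836), were cell cycle (median 0.57, adjusted p = 1.9e-05), cholesterol biosynthesis (0.54, adjusted p = 1.9e-05), oxidative phosphorylation (0.46, adjusted p = 2.3e-05), unfolded protein and amino acid stress (0.35), lysosome (0.49) and melanocyte and melanoma (0.35). Within slide 2 the cell cycle list was at -0.06 and the melanocyte list at -0.08, so 10 of the 12 lists kept their sign in every slide. Against 10000 random lists of genes of like signal, the T and NK cell, B cell, MHC class II, M1 activation and neutrophil lists lay at percentile 0. Lists that were not called also lay low, NF-kB at percentile 0.01, alternative activation at 0.07, IL-10 response at 0.22, the CXCL12 axis at 0.3, MHC class I at 0.49, inflammatory monocyte at 0.59, erythroid at 0.71, early response at 0.98, immune checkpoint at 1.83, endothelial at 2.06 and macrophage identity at 3.2. Among the lists called higher, cell cycle lay at percentile 99.97, oxidative phosphorylation at 99.75, lysosome at 99.67 and cholesterol biosynthesis at 98.66. The melanocyte list lay at percentile 87.3 and the unfolded protein list at 50.0.

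The macrophage identity list, which holds Csf1r and Adgre1, had a median of 0.07 and a mean of -0.20 in TAM and was not called. No member passed in either direction. Those with the smallest p measured lower, Itgam at -2.17 ± 0.74 and Tyrobp at -1.05 ± 0.54, although the median of the list lay above 0. With the slide as a block the median of the list was -0.05, with 0 of 16 higher and 4 lower, and within the slides it was 0.02, 0.23 and -0.63. Its mean signal was 1.03 ± 0.57 (SD, n = 4) in post-sepsis and 1.30 ± 0.40 (SD, n = 3) in naive TAM (exact permutation p = 0.571). The mean of the T and NK cell list was -2.04 ± 0.70 against -0.27 ± 0.54 (exact permutation p = 0.0286), and that of the B cell list -1.67 ± 0.97 against 0.53 ± 0.96 (exact permutation p = 0.0286). The MHC class II list, at 1.29 ± 0.54 against 2.62 ± 0.71, did not pass (exact permutation p = 0.0571). Nor did M1 activation (exact permutation p = 0.0857) or the neutrophil list (exact permutation p = 0.114), whereas the dendritic cell list did (exact permutation p = 0.0286). Cholesterol biosynthesis (2.53 ± 0.15 against 1.83 ± 0.39) passed too, higher in post-sepsis TAM (exact permutation p = 0.0286). So did unfolded protein and amino acid stress (3.05 ± 0.07 against 2.56 ± 0.33, exact permutation p = 0.0286). These permutation p-values were not adjusted for the number of lists tested, and 0.0286 is the smallest possible. They therefore cannot exclude chance over all lists. Interferon response (0.10), hypoxia and glycolysis (0.13), NF-kB cytokines (-0.35), alternative activation (-0.49), IL-10 response (-0.17), immune checkpoint and tolerance (-0.30), the CXCL12 axis (-0.16), inflammatory monocyte (-0.21) and MHC class I presentation (-0.15) were not called. Of these, alternative activation, immune checkpoint and inflammatory monocyte were below 0 within every slide. Medians changed sign between slides for interferon response (-0.33, 0.78 and -0.21), hypoxia and glycolysis (-0.35, -0.02 and 0.67), NF-kB (0.08 on slide 2), IL-10 response (0.24 on slide 2), the CXCL12 axis (0.45 on slide 2) and MHC class I (0.12 on slide 2). Among other lists not called, so did the erythroid list (0.45, -4.44 and -0.33) and the fibroblast and stroma list (-0.74, 2.07 and -0.06). Protein-coding genes had a median change of 0.26 and lincRNA probes one of -0.58. The index of coding against lincRNA signal was 2.82 ± 0.42 (SD, n = 4) in post-sepsis and 2.04 ± 0.34 (SD, n = 3) in naive TAM (exact permutation p = 0.0857).

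**Figure D1:**
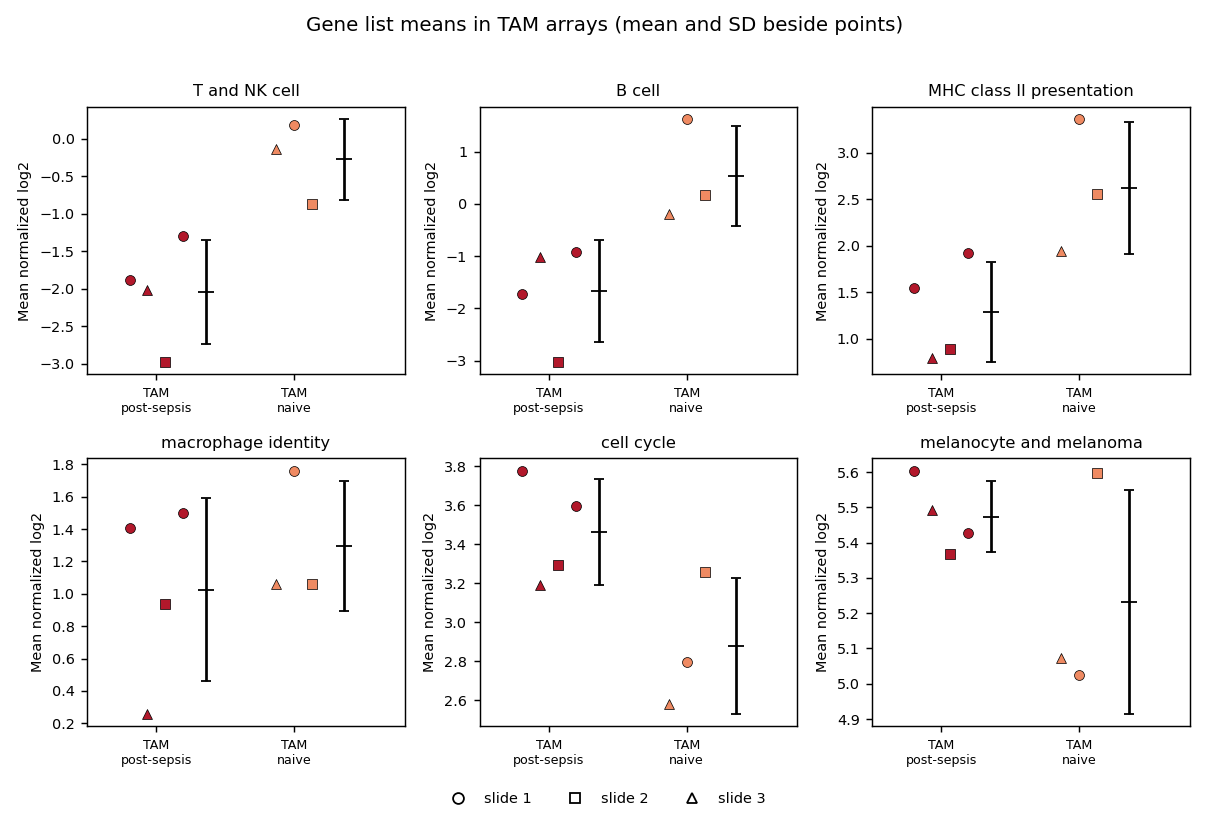
Mean log2 signal of 6 gene lists, relative to the 75th percentile, for each TAM array, with the group mean and SD beside the points and the slide shown by the symbol. The T and NK cell list averaged -2.04 in post-sepsis and -0.27 in naive TAM, while macrophage identity genes averaged 1.03 and 1.30.

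The second comparison asked whether macrophages grown from post-sepsis marrow differed from those of naive marrow. They did, in 3459 of 30903 genes, 1752 higher and 1707 lower. Genes induced by interferon fell, among them Oasl1 (-3.73 ± 0.19), Ifit3 (-3.68 ± 0.21), Ifit2 (-3.60 ± 0.33) and Irf7 (-3.24 ± 0.23), a transcription factor of the interferon response. The fatty acid desaturases Fads2 (at least 38.6-fold), Scd1 (5.97 ± 0.42, adjusted p = 3.3e-07) and Scd2 (5.05 ± 0.22) rose. The monocyte-attracting chemokines Ccl7 (4.55 ± 0.25), Ccl2 (4.27 ± 0.26) and Ccl12 (4.23 ± 0.22) rose, whereas the T cell attractant Ccl5 fell by 7.40 on the log2 scale (SE 0.18, adjusted p = 3.4e-12). The list of the CXCL12 axis and monocyte recruitment, which holds these chemokines, had members going both ways and was not called.

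Further genes with the largest rises were Mgarp (at least 13.4-fold), the mitochondrial adenylate kinase Ak4 (4.88 ± 0.24), Cobll1 (at least 5.19-fold) and the glycine transporter Slc6a9 (4.20 ± 0.23). Those with the largest falls included Retnla, a marker of alternative activation (-6.67 ± 0.70), Saa3 of the acute phase (-4.89 ± 0.20), complement factor B (Cfb, -4.88 ± 0.31), Dnah2 (-4.48 ± 0.22), Bmp2 (-4.46 ± 0.33) and Thbs1 (-4.45 ± 0.25). Adgre4, Stfa1 and Gbp4 fell by at least 12.1-fold, 10.6-fold and 5.82-fold. The sizes for Retnla and Bmp2, above background on 1 of 4 post-sepsis arrays, for Cfb and Il1b, on 2 of 4, and for Scd1, on 2 of 4 naive arrays, are uncertain. Il1b (-3.10 ± 0.21, adjusted p = 2.5e-07), Cd274 (-2.45 ± 0.26, adjusted p = 1.4e-05) and Cxcr4 (-1.93 ± 0.16, adjusted p = 1.8e-06) fell, and Mrc1 rose (1.76 ± 0.24, adjusted p = 1.3e-04). Arg1 (0.45 ± 0.31), Nos2 (-0.03 ± 0.16), Tnf (0.19 ± 0.23), Il10 (-0.05 ± 0.25), Tgfb1 (0.21 ± 0.24) and Vegfa (-0.73 ± 0.25) did not pass, and Arg1 was above background in neither group.

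In the interferon response list 25 of 27 genes fell and 2 did not pass, and all 27 fell adjusted over the list alone (median -1.88, adjusted p = 3.8e-39, and adjusted p = 0.0162 with an estimated correlation). Cell cycle genes rose, 22 of 25, or 23 adjusted over the list alone (median 1.84), with Aurka at 2.33 ± 0.21, Plk1 at 2.25 ± 0.22 and Mki67, a marker of dividing cells, at 2.22 ± 0.22. Cholesterol biosynthesis rose in 17 of 18 genes, the same number adjusted over the list alone (median 1.95), with Lss at 3.26 ± 0.27 and Fdps at 2.93 ± 0.21. In the M1 activation list 8 of 20 fell, 12 adjusted over the list alone, led by Fpr2 (-2.95 ± 0.36) and Acod1 (-2.88 ± 0.17). These 4 lists also passed with an estimated correlation. Within slides 2 and 3, which alone held both groups, the interferon median was -1.81 and -1.96, the cell cycle median 1.94 and 1.88, and the cholesterol median 1.78 and 2.06.

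Hypoxia and glycolysis genes rose in 16 of 24, or 20 adjusted over the list alone (median 1.19, adjusted p = 0.133 with an estimated correlation). The oxygen sensor Egln3 was at 3.19 ± 0.29, Ankrd37 at 2.81 ± 0.21 and the lactate exporter Slc16a3 at 2.55 ± 0.20. In the amino acid stress list 10 rose and 1 fell of 18, with Psat1 of serine synthesis at 3.82 ± 0.21, Chac1 at 3.38 ± 0.24 and Asns at 2.98 ± 0.20 (adjusted p = 0.133 with an estimated correlation). Macrophage identity genes fell in 10 of 17, such as Aif1 (-2.08 ± 0.19) and Cybb, a part of the phagocyte oxidase (-1.96 ± 0.21; adjusted p = 0.126 with an estimated correlation). MHC class I fell in 7 of 15, or 10 adjusted over the list alone, with H2-K1 at -1.30 ± 0.18 and B2m at -1.22 ± 0.21 (adjusted p = 0.133 with an estimated correlation). In the complement and uptake list 8 fell and 2 rose of 18, including C3 (-4.26 ± 0.22) and the uptake receptors Axl (-2.91 ± 0.27) and Mertk (-1.90 ± 0.25; adjusted p = 0.223 with an estimated correlation).

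Lists with smaller shifts were lysosome (5 of 22 fell, adjusted p = 0.294 with an estimated correlation), neutrophil and granule (3 rose and 7 fell of 17, adjusted p = 0.133 with an estimated correlation), and immune checkpoint (3 of 17 fell, adjusted p = 0.223 with an estimated correlation). Early response genes fell in 7 of 14, with Fos at -2.43 ± 0.29 and Dusp1 at -2.30 ± 0.20 (adjusted p = 0.223 with an estimated correlation). In the IL-10 response list 5 rose and 9 fell of 21, with the decoy receptor Il1r2, above background on 1 of 4 naive arrays, at 2.92 ± 0.24 (adjusted p = 0.5 with an estimated correlation), and in oxidative phosphorylation 2 of 23 rose (adjusted p = 0.657 with an estimated correlation). Lists not called were alternative activation (3 rose and 4 fell of 19), MHC class II (2 and 1 of 11), NF-kB (3 and 5 of 21), pro-tumour products (7 and 10 of 23), the CXCL12 axis (4 and 6 of 16), inflammatory monocyte (4 and 3 of 11), dendritic cell (2 and 1 of 11), fibroblast (1 and 0 of 9), endothelial (1 and 0 of 6), B cell (0 and 1 of 9) and melanocyte (0 and 1 of 7). No gene passed in the T and NK cell (13 measured), keratinocyte (8) and erythroid (3, too few for the test) lists.

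Of the genes called, 3451 of 3459 kept their sign within both slides, and 3816 genes passed with the slide as a block. Between other splits of the same 8 arrays up to 2720 genes passed.

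**Figure D2:**
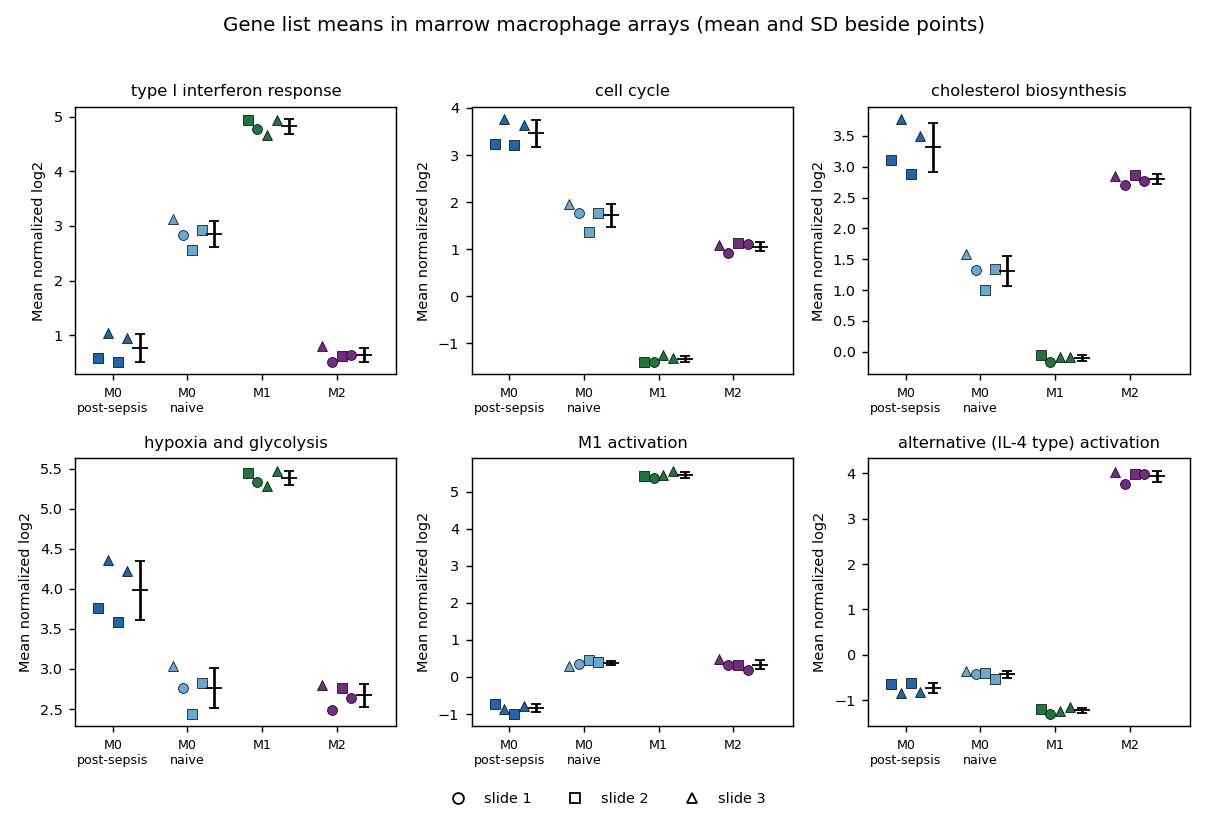
Mean log2 signal of 6 gene lists, relative to the 75th percentile, for each marrow culture array, with the group mean and SD beside the points and the slide shown by the symbol. The interferon list averaged 0.77 ± 0.26 in M0 post-sepsis and 2.86 ± 0.24 in M0 naive, and the cell cycle list 3.46 ± 0.29 and 1.72 ± 0.25 (SD, n = 4).

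The third set of comparisons placed the polarized cultures against M0 naive. In M1 cultures 8157 genes changed, 3834 higher and 4323 lower. Nos2, the inducible nitric oxide synthase, rose by 8.34 ± 0.16 (adjusted p = 1.1e-13) and the cytokine Il1b by 8.30 ± 0.21. Ptgs2 rose at least 1251-fold, Il6 975-fold and Il1a 527-fold as lower bounds. Ubd rose by 12.55 ± 0.47, Inhba, an activin subunit, by 9.83 ± 0.31, and Cxcl3, Mgarp and Slamf1 by at least 453-fold, 196-fold and 129-fold. Among the falls were Tmem176b (-9.80 ± 0.20), S100a9 (-8.26 ± 0.22), Cd5l (-6.83 ± 0.21), Mrc1 (at least 418-fold) and Pcp4l1 (at least 314-fold). Ubd was above background on 2 of 4 naive arrays and Tmem176b on 2 of 4 M1 arrays, so their sizes are uncertain. Cxcl9 (5.89 ± 0.39), Socs3 (6.09 ± 0.22), Il10 (2.86 ± 0.25) and Arg1 (at least 25.7-fold) rose, and Il4ra (0.47 ± 0.20) did not pass.

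M1 activation genes rose in 17 of 20, the same number adjusted over the list alone (median 5.43, adjusted p = 3.8e-05 with an estimated correlation). The NF-kB list had 17 of 21 higher and 1 lower, with Ccl2 at 5.73 ± 0.26, and the MHC class II list 8 of 11 higher, or 9 adjusted over the list alone, with H2-Ab1 at 4.09 ± 0.22. Interferon response genes rose in 23 of 27 (Rsad2 at 3.92 ± 0.23, adjusted p = 0.0652 with an estimated correlation), hypoxia and glycolysis genes in 23 of 24 (Egln3 at 5.40 ± 0.29, adjusted p = 0.0652 with an estimated correlation) and MHC class I in 13 of 15 (Tap1, a peptide transporter, at 3.67 ± 0.32, adjusted p = 0.134 with an estimated correlation). Cell cycle genes fell in 24 of 25, with Ccna2 at -5.87 ± 0.32 and Ccnb2 at -5.12 ± 0.22. Cholesterol genes fell in 10 of 18 and 1 rose (adjusted p = 0.359 with an estimated correlation). Complement and uptake genes fell in 12 of 18 and 2 rose, with Gas6 at -5.34 ± 0.21, C1qa at -4.76 ± 0.25 and Cfb at 6.47 ± 0.31 (adjusted p = 0.316 with an estimated correlation). Cd274 rose by 4.60 ± 0.26. In the IL-10 response list 12 rose and 2 fell of 21 (adjusted p = 0.186 with an estimated correlation).

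In M2 cultures 3501 genes changed, 1426 higher and 2075 lower than in M0 naive. The M2 label names IL-10. Arg1, an enzyme that consumes arginine, rose at least 1085-fold (adjusted p = 8.8e-12), Rbp4 by 10.29 ± 0.25, Fn1 by 9.40 ± 0.27, the chitinase-like Chil4 by 8.47 ± 0.31 and Retnla by 8.44 ± 0.70. Rnase2a (9.41 ± 0.28), Ear2 (8.18 ± 0.17), Ear12 (7.93 ± 0.30), Tmem26 (at least 287-fold) and the fatty acid receptor Ffar4 (at least 60.1-fold) rose too. The fractalkine receptor Cx3cr1 fell by 5.68 on the log2 scale (SE 0.32), and Pcp4l1 (-5.00 ± 0.29), Ifit3b (-4.96 ± 0.22), Ifit3 (-4.87 ± 0.21), Oas2 (-4.28 ± 0.26), Fcrl1 (at least 17.4-fold) and Cxcl1 (at least 6.71-fold) fell. Socs3, a feedback inhibitor downstream of IL-10, fell (-0.79 ± 0.22, adjusted p = 0.032), as did Il10 itself (-1.28 ± 0.25, adjusted p = 0.0029). Mrc1 (2.22 ± 0.24) and Cxcl9 (1.41 ± 0.39) rose, and Il4ra (-0.07 ± 0.20) did not pass. Sizes are uncertain for Rbp4, above background on 1 of 4 naive arrays, for Il10, on 1 of 4 M2 arrays, and for Cx3cr1 and Il1b, on 2 of 4 M2 arrays.

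The alternative activation list had 17 of 19 genes higher in M2, the same number adjusted over the list alone (median 4.27, adjusted p = 1.5e-06 with an estimated correlation), with Ccl24 at 7.74 ± 0.20 and Pdcd1lg2, the other PD-1 ligand, at 5.83 ± 0.30. The IL-10 response list was not called, with 4 higher and 7 lower of 21, or 5 and 8 adjusted over the list alone (median -0.23). MHC class II rose in 8 of 11 (Cd74 at 3.93 ± 0.24, H2-Aa at 3.39 ± 0.26), interferon response genes fell in 24 of 27 (Irf7 at -3.46 ± 0.23), and cholesterol biosynthesis rose in 17 of 18 (Lss at 2.60 ± 0.27). These 3 lists also passed with an estimated correlation. Cell cycle genes fell in 9 of 25, or 15 adjusted over the list alone, with Cenpe at -1.25 ± 0.27 (adjusted p = 0.27 with an estimated correlation), and lysosome genes rose in 7 of 22, with Atp6v0d2 at 3.97 ± 0.19 (adjusted p = 0.275 with an estimated correlation). In the NF-kB list 10 fell and 5 rose of 21, with Il1b at -3.49 ± 0.21 (adjusted p = 0.27 with an estimated correlation). Cxcl10 of the M1 activation list was at -3.58 ± 0.24. Itgax, an integrin of dendritic cells, rose by 6.54 ± 0.22.

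M1 and M2 differed directly in 8777 genes, 4406 higher in M1 and 4371 higher in M2. Higher in M1 were Il1b (11.78 ± 0.21, adjusted p = 1.8e-14), Cfb (10.10 ± 0.31), the formyl peptide receptor Fpr1 (9.91 ± 0.18) and Ly6a (9.42 ± 0.29). Higher in M2 were Fn1 (-10.34 ± 0.27), Retnla (-10.16 ± 0.70), Ear2 (-9.83 ± 0.17), Chil3 (-9.59 ± 0.22) and Arg1 (-5.40 ± 0.31). Nos2 (6.84 ± 0.16), Socs3 (6.88 ± 0.22) and Il10 (4.13 ± 0.25) were higher in M1. Ear2 was above background on 1 of 4 M1 arrays, Il10 on 1 of 4 and Il1b and Egln3 on 2 of 4 M2 arrays, so these sizes are uncertain. All 27 interferon genes were higher in M1 (Irf7 at 6.87 ± 0.23, adjusted p = 0.0167 with an estimated correlation), as were 17 of 20 M1 activation genes, 19 of 21 NF-kB genes and 22 of 24 hypoxia genes (Egln3 at 7.40 ± 0.29, adjusted p = 0.0956 with an estimated correlation). Lower were 16 of 19 alternative activation genes, all 18 cholesterol genes (adjusted p = 0.0594 with an estimated correlation) and 24 of 25 cell cycle genes (adjusted p = 0.0554 with an estimated correlation). Calls that kept their sign in every slide numbered 8139 for M1, 3496 for M2 and 8754 for M1 against M2. With the slide as a block 8438, 3903 and 8970 genes passed.

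On the M1-minus-M2 signature, taken from the M1 and M2 arrays themselves, M0 post-sepsis arrays scored lower than M0 naive arrays. The scores were -2.15 ± 0.24 and -1.55 ± 0.06 (SD, n = 4 each), a difference of -0.59 with an exact permutation p of 0.0286, the smallest possible. The M1 genes alone averaged -2.71 ± 0.12 and -1.98 ± 0.13 (exact permutation p = 0.0286), with 41 of 100 lower and 11 higher, whereas the M2 genes differed by -0.13 (exact permutation p = 0.343), with 24 higher and 26 lower. Post-sepsis TAM scored -0.43 ± 0.45 (SD, n = 4) and naive TAM -0.02 ± 0.32 (SD, n = 3), which did not differ beyond the spread (exact permutation p = 0.257). The M1 genes averaged -1.16 against -0.76 in TAM (exact permutation p = 0.543) and the M2 genes -0.73 against -0.74 (exact permutation p = 0.914). Against all other genes, the M2 genes were called higher in post-sepsis TAM at the preset correlation (median 0.25 over 80 genes, 0 passing in limma, adjusted p = 0.0113) and not with an estimated correlation (adjusted p = 0.784 with an estimated correlation). That median was no larger than the 0.26 of all protein-coding genes.

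**Figure D3:**
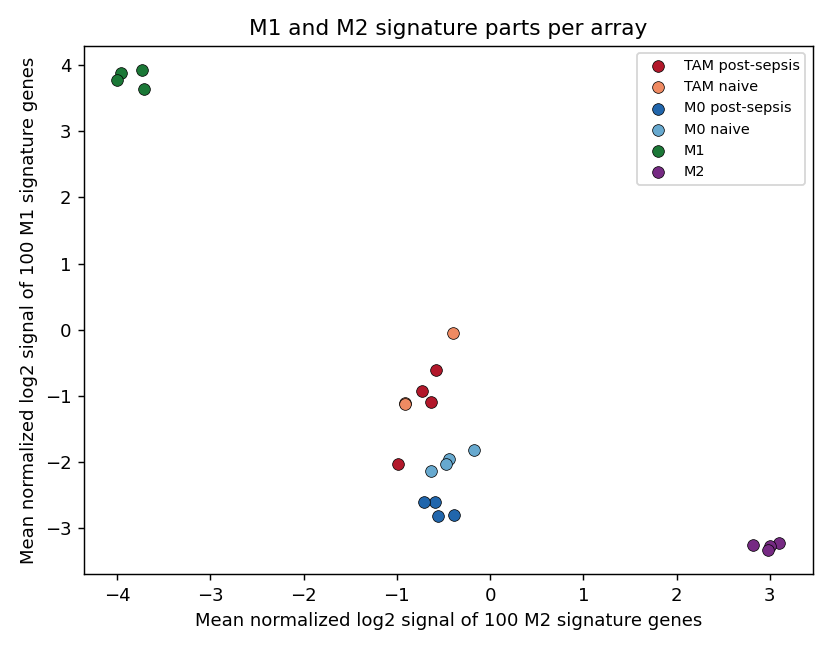
Mean log2 signal, relative to the 75th percentile, of the 100 M2 signature genes (x axis) and the 100 M1 signature genes (y axis) in each of the 23 arrays, with the group shown by the colour. M0 post-sepsis arrays averaged -2.71 on the M1 genes and M0 naive arrays -1.98.

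The next comparison set TAM of naive mice against M0 macrophages of naive marrow, which differ in origin, isolation and culture. Of 32382 genes 4807 were higher and 6255 lower in TAM. Genes of pigment cells were higher, with Dct at least 17882-fold, Tyrp1 at least 9186-fold, Pmel at 11.98 ± 0.28 and Mlana at 11.53 ± 0.40. Genes of macrophages were lower, including the F4/80 antigen Adgre1 (-7.53 ± 0.37), the growth factor receptor Csf1r (-6.33 ± 0.36), Lyz2 (-7.80 ± 0.51) and Trem2, a lipid-sensing receptor (-7.98 ± 0.31). Further genes lower in TAM were Cd5l (-10.06 ± 0.45), Npy (-9.23 ± 0.39), Ms4a7 (-9.08 ± 0.29), Gpr162 (-7.67 ± 0.25), Cd200r1 (at least 142-fold) and C1qc (-7.46 ± 0.35), and Hba-a1, a globin, was higher (11.48 ± 0.79). Npy was above background on 1 of 3 TAM arrays, so its size is uncertain.

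The melanocyte and melanoma list was higher in 11 of 12 genes (median 8.46, adjusted p = 0.0052 with an estimated correlation) and the endothelial list in 8 of 11 (Cdh5 at 6.31 ± 0.49). Fibroblast and stroma genes were higher in 14 of 15 (Col3a1 at 10.55 ± 0.58, Dcn at 9.03, adjusted p = 0.0562 with an estimated correlation), and T and NK cell genes in 14 of 17 with 1 lower (Cd3g at 4.26 ± 0.85, adjusted p = 0.243 with an estimated correlation). B cell genes were higher in 8 of 11 (Ms4a1 at 4.48 ± 1.20, adjusted p = 0.243 with an estimated correlation) and erythroid genes in 4 of 5 (adjusted p = 0.227 with an estimated correlation). Macrophage identity genes were lower in 15 of 17 and lysosome genes in 19 of 22, with Psap at -5.30 ± 0.34, and both passed with an estimated correlation. Complement and uptake genes were lower in 15 of 18 (adjusted p = 0.0655 with an estimated correlation), interferon genes in 25 of 27 with 1 higher (Ifit3 at -4.25 ± 0.28, adjusted p = 0.0768 with an estimated correlation) and MHC class I in 14 of 15 (H2-D1 at -3.38 ± 0.26, adjusted p = 0.0698 with an estimated correlation). H2-Eb1 was higher (2.75 ± 0.32), within an MHC class II list that was not called (7 higher and 1 lower of 11). Hypoxia genes were higher in 18 of 24 with 1 lower (adjusted p = 0.227 with an estimated correlation), and cell cycle genes in 17 of 25 with 1 lower (adjusted p = 0.245 with an estimated correlation). Early response genes were higher in 9 of 14 with 2 lower (adjusted p = 0.297 with an estimated correlation), with Hspa1a at 6.02 ± 0.58 and Fosb at 5.59 ± 0.38. The keratinocyte list had 1 gene higher and 1 lower of 10. Cd3g and Cdh5 were above background on 1 of 4 M0 arrays and Col3a1 on 2 of 4, so their sizes are uncertain.

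Il1b (4.98 ± 0.57), Il6 (at least 235-fold), Arg1 (at least 28.4-fold), Cxcl12 (at least 35.4-fold) and its scavenger receptor Ackr3 (at least 55.3-fold) were higher in TAM, and Mrc1 was lower (-4.76 ± 0.37). Beside M0, the TAM arrays were high in genes of pigment, stromal and endothelial cells and low in macrophage identity genes. Differences in Il1b and the other genes named here, and the TAM changes and scores above, therefore cannot be assigned to macrophages. Of the genes called, 10867 of 11062 kept their sign within every slide, and 11262 passed with the slide as a block.

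**Figure D4:**
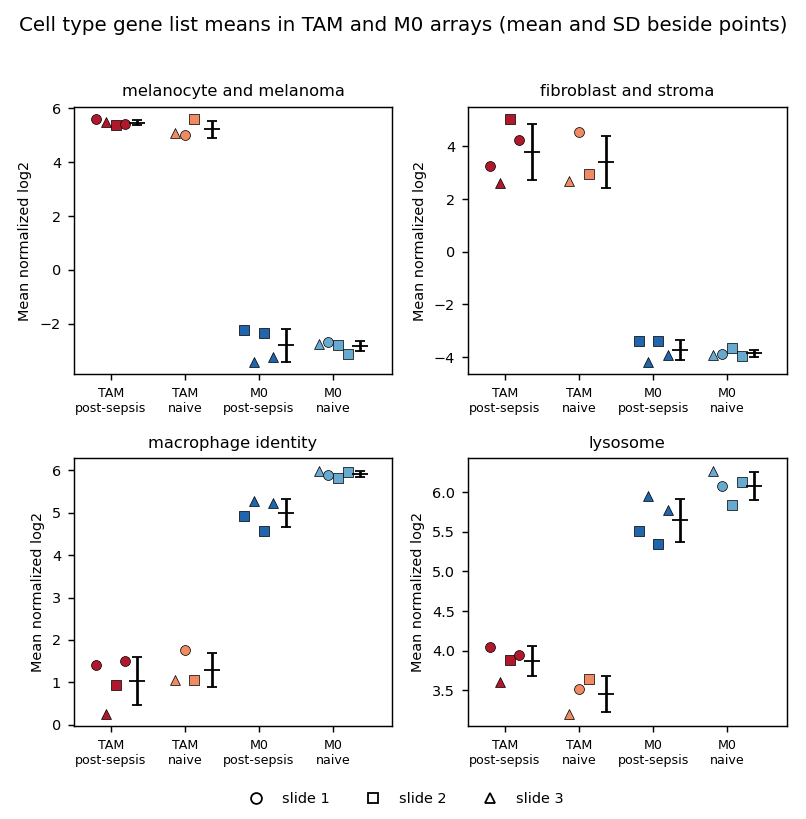
Mean log2 signal of the melanocyte, fibroblast, macrophage identity and lysosome lists, relative to the 75th percentile, for each TAM and M0 array, with the group mean and SD beside the points and the slide shown by the symbol. The melanocyte list averaged 5.47 ± 0.10 in post-sepsis (SD, n = 4) and 5.23 ± 0.32 in naive TAM (SD, n = 3).

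The last comparison tested whether the sepsis effect differed between TAM and M0. The fit took a common spread for TAM and culture arrays. For Ccl2 the SE of the difference was 0.77, below the 0.84 of the TAM effect in its own fit. For Ifit2 the SE of the difference was larger (0.50 against 0.35), so genes went both ways. Adjusted p may thus be too small for genes that vary more in TAM than in the cultures. In this fit the effect was called different in 1871 of 32382 genes, with 1120 more positive in TAM and 751 more negative. Such a difference need not be a change in TAM, where no gene passed in the main fit. Ccl5, for one, measured lower in both, at -1.18 ± 0.39 in TAM and by more in M0, and Scd1, Fads2, Ak4 and Mgarp rose in M0. The chemokine Ccl5 (6.22 ± 0.38, adjusted p = 1.6e-08), the interferon-induced genes Ifit2 (4.78 ± 0.50) and Ifit3 (4.36 ± 0.38), and Retnla (5.96 ± 0.91) had a more positive effect in TAM. The desaturases Scd1 (-5.06 ± 0.62) and Fads2 (-5.12 ± 0.64), the kinase Ak4 (-4.69 ± 0.34), Mgarp (-5.81 ± 0.40) and the dendritic cell lectin Cd209a (-5.86 ± 0.79) had a more negative effect in TAM. Ccl2 differed as well (-3.90 ± 0.77, adjusted p = 0.0048), and so did Cd5l (5.81 ± 0.62), Saa3 (5.76 ± 1.37), Cfb (5.63 ± 0.99), Cp (4.92 ± 0.58), Adgre4 (4.44 ± 0.64), Il1r2 (-4.68 ± 0.62), Klrd1 of NK cells (-4.87 ± 0.60) and Bank1 of B cells (-4.82 ± 0.89). Fads2, Mgarp, Adgre4, Cd209a and Klrd1 were above background on no array of an M0 group, Retnla and Il1r2 on 1 of 4, and Scd1, Cfb and Il1b on 2 of 4, so the sizes of their differences are uncertain. No difference was called for Cxcr4 (0.19 ± 0.45), Cd274 (1.42 ± 0.52), Il1b (1.42 ± 0.77), Mrc1, Arg1, Vegfa, Il10, Tnf, Tgfb1, Nos2 and Cxcl12.

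At the preset correlation 16 lists were called, and none held with an estimated correlation, where adjusted p ran from 0.088 to 0.712. The interferon list was more positive in TAM in 22 of 27 genes, or 25 adjusted over the list alone (median 2.04, adjusted p = 0.088 with an estimated correlation). More negative in TAM were cholesterol biosynthesis (10 of 18, adjusted p = 0.312 with an estimated correlation), cell cycle (12 of 25, Mki67 at -1.88 ± 0.31, adjusted p = 0.312 with an estimated correlation) and hypoxia and glycolysis (10 of 24, adjusted p = 0.356 with an estimated correlation). T and NK cell genes were more negative in 8 of 17, or 13 adjusted over the list alone (Cd3g at -4.19 ± 1.16, above background on 1 of 4 arrays in each M0 group, adjusted p = 0.356 with an estimated correlation). MHC class II genes were more negative in 7 of 11 (H2-Eb1 at -2.60 ± 0.44, adjusted p = 0.312 with an estimated correlation) and B cell genes in 2 of 11, or 8 adjusted over the list alone (Cd79a at -2.27 ± 0.62, adjusted p = 0.356 with an estimated correlation). Complement and uptake genes were more positive in 10 of 18 (adjusted p = 0.312 with an estimated correlation) and lysosome genes in 7 of 22 (adjusted p = 0.253 with an estimated correlation).

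The median effect over all genes was -0.33, with 0.05 in protein-coding genes and -0.76 in lincRNA probes, so single changes stand against that shift. With the slide as a block 1853 genes passed. Quantile scaling moved the median to -0.04 and gave 2196 more positive and 837 more negative genes. Without 1 array at a time the count ranged from 927 to 5850. It was lower than 1871 by more than 1.5 times without TAM post-sepsis replicate 1 (1237) or 3 (1086), TAM naive replicate 1 (927) or 3 (1200), M0 post-sepsis replicate 1 (1070), or M0 naive replicate 2 (1211) or 4 (998). It was higher without TAM post-sepsis replicate 2 (5850), TAM naive replicate 4 (3026), or M0 post-sepsis replicate 2 (3538) or 4 (4090).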

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

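The tests that regroup the arrays were written before the results were seen, except for the regrouping within slides. That test and all tests of the patterns below were chosen after seeing the results. In M0 naive, replicate 4 had 62.0% of probes well above background, where the other 3 arrays had 64.7% to 65.2%. It was picked out as far from the others. Since 30 combinations of a measure and a group were tested for such an array and chance gives about 1 in 20, this may be chance. The comparison of sepsis effects was listed because 1871 genes were called as differing between TAM and M0. The value table was listed because 22 of its columns matched the scanner file of another sample, which the labels do not mention.

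Regrouping tested whether chance can be excluded for each count of genes. For post-sepsis against naive TAM it could not be tested, because the real count was 0 in limma (10928 unadjusted) and any split, here 35 of 35, gives at least that. The highest other split gave 9458, with post-sepsis replicate 2 placed among the naive arrays. A split calling that many genes points to a structure of these samples in which that array stands apart from its group, and without it 9709 genes were called in limma. The same split parted the arrays by the index of coding against lincRNA signal, 2.95 to 3.14 against 1.67 to 2.33. The next split, with 4262 genes, moved naive replicate 4 (index 2.33) to the high side and also followed the index. Whether the index accounts for these counts was not tested. Within slides, 1 of 12 splits reached the real count of 9978 and the highest other split gave 0, but 12 splits are too few to exclude chance.

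For M0 post-sepsis against naive 1 of 35 splits, the real one, reached 3459, which is the smallest share this test can give. Chance was thus excluded only at the limit of the test, and the highest other split of the same arrays gave 2720. That other split parted post-sepsis replicates 1 and 3, on slide 2, from replicates 2 and 4, on slide 3. It also parted naive replicates 3 and 4, on slide 2, from replicates 1 and 2, on slides 3 and 1. Within each group the split thus followed the slide, in opposite directions, so that each side held 2 arrays of slide 2. Chance was also excluded for M1 (1 of 35, real 8157, highest other 0), for M2 (1 of 35, real 3501, highest other 2) and for M1 against M2 (1 of 35, real 8777, highest other 0). For TAM naive against M0 naive 1 of 35 splits reached 11062, and the highest other split, with M0 naive replicate 3 on the TAM side, gave 10839. For the difference between sepsis effects 4 of 100 splits reached 1871 and the highest other split gave 5512, several times the real count, so the arrays have a structure that the groups do not explain.

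The first pattern was the lower level of 38 T and NK cell, B cell and MHC class II genes in post-sepsis TAM, with a median of -1.80. With the index of coding against lincRNA signal as a covariate the median was -1.84 (median SE 0.66). The index itself differed between the groups, with 3 post-sepsis arrays beyond all naive arrays. The covariate also moved other lists both ways, NF-kB from -0.35 to -1.90 and erythroid from -0.88 to 0.55. This fit therefore cannot decide whether an array-wide axis of signal was the cause. The median of macrophage identity genes was 0.0723 (median SE 0.50), which argues against an even dilution of all immune cells by tumour cells as the whole cause. It was -0.86 with the index as a covariate and -0.63 within slide 3, so a part of that dilution stays open. With the slide as a block 4 of 16 macrophage identity genes were lower, a share near that over all genes. Within slides the median of the 38 genes was -2.28, -2.09 and -1.18, the smallest being -1.18, which argues against the slide. A lower share of lymphocytes and antigen-presenting cells in the isolated fraction may remain as an explanation, and it could be technical, from isolation, or biological, since no test here separates them.

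The second pattern was the alternative activation profile of M2 cultures whose label names IL-10. The IL-10 response list had a median of -0.23 in M2, which is consistent with an IL-4 receptor ligand in these cultures as a candidate explanation. An exchange of M1 and M2 arrays was excluded, since M1 activation genes had a median of 5.43 in the M1 arrays. The stimulus itself was not measured.

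The third pattern was the lower interferon response in M0 post-sepsis than in M0 naive. M0 post-sepsis exceeded M2 by a median of 0.27 over this list (median SE 0.23, 7 higher and 4 lower of 27), which cannot tell whether an interferon response may be held by the M0 naive cultures alone. The smallest median within a slide was -1.81, beside -1.96 on the other slide, so the slide was excluded as the cause.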

How the results depend on the processing

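The index covariate, centring on protein-coding genes, the rematched value table and the list tests against protein-coding genes were chosen after seeing the data. No named gene was called in the opposite direction under any alternative in the comparisons other than post-sepsis against naive TAM, whose named genes were not followed in this way. Calls of named genes were lost, with 53 of 89 kept for the difference between sepsis effects with TAM naive replicate 2 added and 62 of 89 with the index as a covariate, and 80 of 93 for M0 with only the compared groups in the fit. Counts of genes for TAM naive against M0 naive stayed within 1.5 times of 11062 under all alternatives but the value table. With the value table as deposited, 0 genes were called in limma in every comparison, with unadjusted counts such as 510 for M0, 355 for M1, 2667 for M2, 2544 for M1 against M2, 79 for TAM naive against M0 naive and 141 for the difference between sepsis effects, and it gave no signature value. The mismatch of 22 of its columns with their own samples shows the cause.

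For TAM the count was 0 under 12 of 17 alternatives. It was 9978 with the slide as a block, 9820 with the replicate number as a block, 14939 with array weights, 3722 with all 23 arrays in the fit, and 6282 at unadjusted p with a 2-fold change. Leaving out arrays gave 0 to 9709, the latter without post-sepsis replicate 2. The cause was not tested, other than for the looser threshold, which calls more by construction.

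For M0 (3459) the count was 9932 with array weights, 2193 with a 2-fold minimum, 1580 with only the compared groups in the fit and 5266 with the index as a covariate, and 2590 to 3576 without single arrays. M1 (8157) had 15481 with array weights and 7098 to 7808 without single arrays. M2 (3501) had 12280 with weights, 2259 with a 2-fold minimum and 2470 to 3695 without single arrays. M1 against M2 (8777) had 13457 with weights and 7586 to 8507, and TAM naive against M0 naive 9339 to 12520, without single arrays. The fits of array weights gave convergence warnings, and a 2-fold minimum lowers counts by construction. Otherwise the cause was not tested.

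The difference between sepsis effects (1871) was the least stable. It was 3033 with quantile scaling, 6607 with array weights, 6854 at unadjusted p with a 2-fold change, 728 with TAM naive replicate 2 added, 917 with the index as a covariate and 3579 with the rematched value table (2643 more positive, 936 more negative). The cause was not tested. Without single arrays it ran from 927 to 5850, and the report gives the value for each array that moved it by more than 1.5 times.

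The M0 signature difference of -0.59 ran from -4.63, in percentile points with rank scoring, to -0.45, with slide means removed, over 8 alternatives, all at an exact permutation p of 0.0286. On the log2 scale it was -0.95 with the rematched value table and -0.89 with 200 genes each way. It ran from -0.68 to -0.50 without single arrays, and its exact permutation p was 0.0571 without M0 naive replicate 2 (-0.58) or 3 (-0.57), where 4 arrays against 3 remain. The TAM difference ran from -0.54 to -0.21 without single arrays, and from -3.51, in percentile points, to -0.18 over 9 alternatives, and its p stayed above 0.05. Rank scoring has another unit by construction. List tests made 104 calls in the main fits, 20 with an estimated correlation, 117 in fry and 98 to 102 under the other alternatives, counts that include lists not called before. Of the 12 TAM calls, fry kept 1, the replicate block 7, quantile scaling 8, TAM naive replicate 2 added back 8, protein-coding genes as the background 10 and the slide block 11.

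Normexp background moved the median change of all genes to -0.16 in TAM, 0.14 in M0 and 0.15 in TAM naive against M0 naive, and quantile scaling moved it to 0.08, 0.00 and -0.07. Replicate numbers did not pair arrays, since not every sample correlates best with its own number (M0 1 of 4, M1 3 of 4). With the replicate number as a block, 3327 genes passed in M0, 7979 in M1, 3437 in M2, 8609 in M1 against M2, 10887 in TAM naive against M0 naive and 1640 for the difference. With this block the signature differences were -0.59 in M0 and -0.18 in TAM. In simulated data recovery at a log2 change of 2 was lowest for the difference (35%) and for TAM (46%).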

Other observations

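M0 macrophages of post-sepsis marrow were also set against the M2 cultures, a comparison chosen after seeing the results. Cell cycle genes were higher in M0 post-sepsis in 23 of 25 (median 2.62), hypoxia and glycolysis genes in 16 of 24 with 1 lower (median 1.02), and inflammatory monocyte genes in 6 of 11 with 1 lower (median 0.95). Cholesterol genes were higher in 6 of 18 (median 0.43). Alternative activation genes were lower in 16 of 19 (median -3.93), MHC class II genes in 8 of 11 (median -1.51) and lysosome genes in 11 of 22 (median -0.56). Both groups were n = 4 in the same limma fit.

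The TAM naive array that the submitters left out had an index of coding against lincRNA signal of 0.18, where the other TAM naive arrays had 1.67, 2.13 and 2.33. Its M1-minus-M2 signature score was -0.39. Its 75th percentile of processed intensity was 49.2, and its lowest correlation with another array of its group was 0.581.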
